A study of Homo sapiens with 6 samples.

How the data were processed

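RNA-seq gene counts of 6 NB4 libraries were used: a control construct and 2 hairpins against SMARCD2, each in DMSO and in ATRA. Per the labels' protocols, RNA was purified with GeneJET columns and libraries were made with the NEBNext Ultra RNA kit, and the series description, which speaks of chromatin accessibility, says that samples were sequenced 2 times as technical replicates. The 2 count columns per library were taken as these runs. Per the submitters' processing notes, bcl2fastq, STAR, Picard 2.5.0 and DESeq2 were used with the genome build GRCh37.p13, with their roles not stated, and how reads were assigned to genes and whether strand was used is not given in the sources used here. The authors deposited 1 table per treatment, which lists 12752 genes for DMSO and 12838 for ATRA. Each holds raw counts per gene in 2 columns per library, taken here as sequencing runs, in whole numbers with no normalization. Per the file headers, the deposited tables also give the authors' log2 fold change, smaller than the ratio of the normalized counts and so shrunken. The authors' p-value and adjusted p-value for knockdown against control are in the same deposited tables. The 12 columns of normalized copies were not used. They outnumber the 6 libraries, so the authors' test may have taken each run as a sample, which would count runs as replicates. Genes with few counts are absent from each table and the filter is not stated.

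Counts of the 2 runs of a library were summed, and runs were never counted as replicates. Run 1 gave 54.6% of the control library in DMSO and 53.1% of that in ATRA, but between 70.6% and 80.7% of the knockdown libraries. The mix of runs thus differed between control and knockdown in both treatments. The runs of a library differed by more than counting error (chi-square per degree of freedom 5.32 to 7.07). Library totals ran from 29291209 to 58099733 counts, and the 10 most abundant genes took between 4.66% and 5.67%. The tables share 12301 genes, and 537 were only in the ATRA table and 451 only in the DMSO table. Comparisons across treatments used the shared genes, with the full table totals as library sizes. Fits within 1 treatment also covered the genes listed in 1 table.

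The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Counts were filtered with filterByExpr by group, scaled with TMM and tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The group fit had 4 groups, with 1 control library and 2 knockdown libraries per treatment, so that its 2 residual degrees of freedom come from the spread between the hairpins, and the lone control libraries are assumed to vary like the knockdown libraries. It gave knockdown against control in each treatment, ATRA against DMSO in each state, and the difference in ATRA response. The ATRA response over the 3 constructs was fitted with knockdown state and treatment, and the hairpins were compared over the 4 knockdown libraries with treatment as a term (1 residual degree of freedom). Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Leaving out a knockdown library leaves 1 residual degree of freedom in the group fit, from the 2 hairpins of the other treatment, and the lone library is assumed to vary like them. CPM values use TMM-scaled library sizes. No genomic coordinates are given.

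The hairpin titles pair the treatments, since the same hairpin appears in both. The difference between the hairpins in DMSO correlated with that in ATRA with r = 0.26 across all genes. Across genes with a mean of at least 10 CPM it was 0.27. Over those genes only, deviations of each construct in DMSO correlated with its own in ATRA. There r was 0.08 for the control, 0.19 for hairpin 1 and 0.21 for hairpin 2. A fit with the hairpin as a block (1 residual degree of freedom) is given beside a result where it changed the call of a named gene or list or moved a count by more than 1.5 times. Its error leaves out what the hairpins differ by in both treatments. The labels do not say whether the DMSO and ATRA libraries of a hairpin came from the same transduced cells, and every call gained with the hairpin term rests on that pairing. For knockdown against control within a treatment, even a true pairing does not supply the spread between constructs, which this fit removes. Its p-values there can understate the error, and calls gained with it are given as values of that fit only.

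Gene lists were 20: azurophil granule, specific granule, gelatinase granule and secretory vesicle, NADPH oxidase, retinoic acid target, myeloid transcription factor, monocyte and macrophage marker, stem and progenitor marker, eosinophil, basophil and mast cell marker, erythroid and megakaryocyte marker, lymphoid marker, subunits of BAF, PBAF and ncBAF, cell cycle, MYC target and ribosome biogenesis, interferon response, chemokine and cytokine, p53 target and apoptosis, unfolded protein and integrated stress response, sterol synthesis, and mitochondrially encoded transcript. The 19 with at least 5 measured genes were tested with limma's camera (preset correlation 0.01) for knockdown in each treatment, ATRA over the constructs and the difference in response, with adjustment over the 76 tests, and again with an estimated correlation and with fry. Lists of hypoxia response and metallothionein genes were written after the gene tests had been seen, and their medians were set beside 10000 random lists matched on mean expression in 20 bins. Random lists do not allow for correlation between the genes of a list, and camera was not run on these lists.

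The genes named were SMARCD2 and, for each of those 4 comparisons, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM and 1 direction in every hairpin or construct. Places left open went, as values only, to genes with the largest smaller ratio of the 2 hairpins. From each list came up to 4 called members of smallest p, or up to 2 members with the largest change where none was called, and SMARCD1, SMARCD3 and CEBPE could be named too. The text gives part of the genes this rule yields, and says where a gene was chosen after its values were seen. The sample groups, tests, gene lists, this rule and the first set of alternatives were chosen before the data were examined.

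The tests were checked on simulated counts for 12301 genes with 200 changed. Both hairpins were given the same fold. The rates may be lower for genes on which the hairpins differ, or where fewer genes change, so they do not show that uncalled genes were unchanged. For knockdown in DMSO, 46.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 90.9% of those changed 4-fold were called, with 9 unchanged genes called. For knockdown in ATRA these were 43.3%, 74.6% and 95.5%, with 10 unchanged. For ATRA over the constructs they were 70.1%, 80.6% and 98.5%, with 12 unchanged, and for the difference in response 9%, 53.7% and 80.3%, with 10 unchanged. Among 20 simulated lists of 30 genes for knockdown in DMSO, camera called the 1 list raised 1.3-fold (adjusted p = 1.3e-48; 0.0693 with an estimated correlation) and 1 unchanged list.

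Hairpins compared with the same control library share its chance values, so 100 simulated pairs of unchanged hairpins against that control gave the correlation and covariance to set beside the observed ones. GC content and transcript length came from GENCODE v29 transcripts (GRCh38), used for names and composition alone, for 13251 of 13289 symbols (99.7%). Alternatives planned beforehand were DESeq2 size factors, total counts, no filter, at least 10 counts in every library, DESeq2, limma-voom, leaving out each library, the 3 libraries of 1 treatment, an additive fit, the hairpin block and other set tests. Alternatives added after the data were seen were each run alone, runs thinned to equal depth, each run as its own library, a GC and length correction (splines with 5 degrees of freedom), and that correction with the block. For gene lists the correction was made on limma-voom values, while the main list test used the edgeR counts. The step to voom and the correction were not separated for lists.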

Results

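The data were RNA-seq gene counts from NB4, a human acute promyelocytic leukemia cell line that matures toward granulocytes under all-trans retinoic acid (ATRA). The cells carried a control construct or 1 of 2 short hairpins against SMARCD2, a subunit of the BAF (SWI/SNF) chromatin remodelling complex. Inherited loss of SMARCD2 is known as a cause of neutrophil specific granule deficiency. Each construct was given ATRA at 1 µM or the vehicle DMSO, which made 6 libraries, 1 control and 2 knockdown libraries per treatment. The length of treatment is not given in the sources used here. The control libraries held 29291209 counts in DMSO and 29521141 in ATRA, hairpin 1 held 58099733 and 51324652, and hairpin 2 held 41846630 and 44370146, each summed over 2 count columns taken as sequencing runs of the same library. A gene was tested where both deposited tables listed it, which left 12301 genes.

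SMARCD2 stood at 95.5 CPM (counts scaled to library size) in the control in DMSO, against 39 with hairpin 1 and 25.7 with hairpin 2. In ATRA it stood at 122 CPM in the control, 64.2 with hairpin 1 and 35.6 with hairpin 2. It was below the control in 4 of 4 knockdown libraries, with a log2 fold change of -1.55 ± 0.32 in DMSO (SE, n = 2 knockdown and 1 control; adjusted p = 0.39, edgeR quasi-likelihood test) and of -1.29 ± 0.31 in ATRA (adjusted p = 0.32). The spread between the hairpins set these errors, since SMARCD2 was lower with hairpin 2 than with hairpin 1 by a log2 difference of -0.73 ± 0.07 (adjusted p = 3.0e-06). With the hairpin as a term in the fit, SMARCD2 had log2 fold changes of -1.60 in DMSO (adjusted p = 1.8e-08) and -1.35 in ATRA (adjusted p = 1.2e-07). That fit pairs the treatments and removes what the hairpins differed by in both, so its p-values leave out the spread between constructs. The authors' deposited tables list log2 fold changes of -0.96 in DMSO (adjusted p = 1.8e-21) and -0.40 in ATRA (adjusted p = 0.0073). Their test may have counted runs as replicates. Of its paralogs in the complex, SMARCD1 had log2 fold changes of -0.12 ± 0.08 in DMSO and -0.07 ± 0.09 in ATRA. SMARCD3 had -0.32 ± 0.15 in DMSO and -0.86 ± 0.17 in ATRA (adjusted p = 0.26; 0.0012 with the hairpin term). In DMSO, SMARCD1 stood at -0.029 without hairpin 1 and -0.20 without hairpin 2, and SMARCD3 at -0.46 and -0.18. SMARCD1 in ATRA stood at -0.038 without hairpin 1 and -0.099 without hairpin 2.

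**Figure D1:**
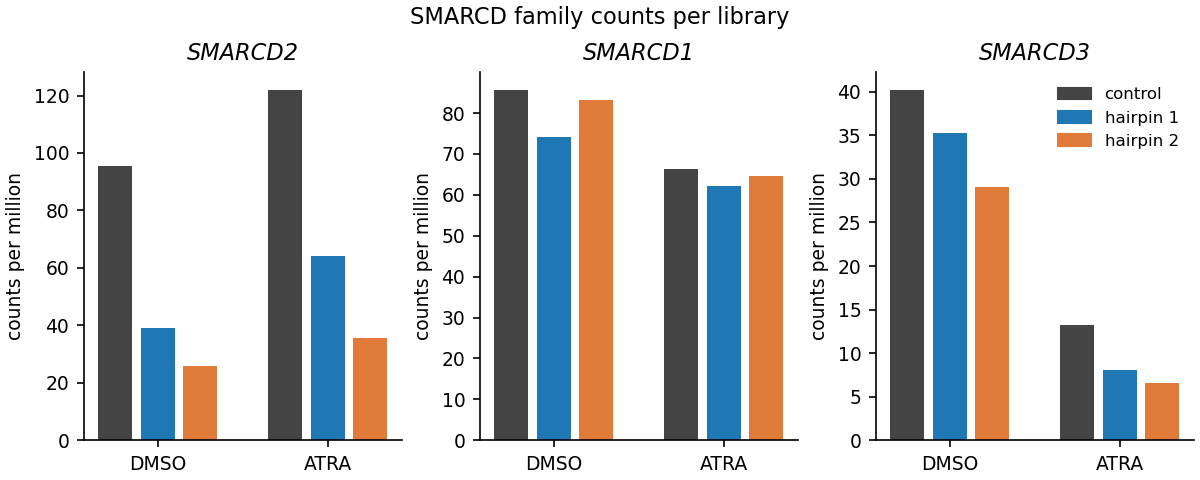
CPM of SMARCD2, SMARCD1 and SMARCD3, 1 bar per library, by treatment. SMARCD2 stands at 95.5 in the control against 39 and 25.7 in DMSO, and at 122 against 64.2 and 35.6 in ATRA.

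The comparison of ATRA with DMSO asked which genes the differentiation stimulus changed, over the 3 constructs (n = 3 against 3). S100A9, a calprotectin subunit, rose from 0.462 ± 0.162 to 557 ± 100 CPM (mean ± SD, log2 fold change 10.11 ± 0.22, adjusted p = 4.6e-09). The sialic acid receptor gene SIGLEC1 rose by 9.83 ± 0.15, the chemokine gene CCL2 by 9.44 ± 0.09, the bactericidal protein gene BPI by 9.10 ± 0.14, the ubiquitin ligase subunit gene ASB2 by 8.89 ± 0.11 and the SRC family kinase gene FGR by 8.77 ± 0.11. NCF1 rose by 9.57 ± 0.09 and the defensin gene DEFA1B by 8.78 ± 0.22, both uncertain in size because reads of near-identical copies can be shared. CYTL1, a cytokine-like gene of immature cells, fell from 406 ± 59.1 to 0.445 ± 0.158 CPM (-9.93 ± 0.17, adjusted p = 1.4e-09). The telomerase gene TERT fell from 234 ± 13.1 to 3.73 ± 1.29 CPM (-5.97 ± 0.18, adjusted p = 1.8e-08). Other large decreases were the scavenger receptor gene STAB1 at -8.18 ± 0.11, ZBTB16 at -6.05 ± 0.24, NOG at -5.94 ± 0.20, DAB2IP at -5.85 ± 0.27, MEGF6 at -5.81 ± 0.08 and SOX18 at -5.78 ± 0.15. In all, 4450 genes were higher and 4650 lower, 1469 and 1142 of them by at least 2-fold. The counts of higher and lower genes were 3610 and 3642 in the control alone, a difference between 1 library and 1 whose spread came from the knockdown libraries, and 4252 and 4351 in the knockdown cells. Scaling to total counts instead of TMM shifted the median of all genes by -0.13 and gave 3637 higher and 5722 lower over the constructs, 2914 and 4610 in the control and 3480 and 5338 in the knockdown cells.

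Gene lists fixed beforehand gave the shape of the ATRA response. Of 32 interferon response genes, 32 rose (median log2 fold change 3.19, camera adjusted p = 1.29e-32; adjusted p = 0.581 with an estimated correlation), with IFI27 up by 5.89 ± 0.08, RSAD2 by 5.62 ± 0.06, OAS3 by 5.22 ± 0.10 and IFIT2 by 3.57 ± 0.09. Of 25 retinoic acid targets, 22 rose and 3 fell (median 3.79, adjusted p = 1.32e-27; adjusted p = 0.543 with an estimated correlation), among them HIC1 by 7.41 ± 0.09, ID2 by 5.84 ± 0.07 and TNFAIP2 by 4.15 ± 0.06. All 9 measured genes of the NADPH oxidase list rose (median 1.54, adjusted p = 8.36e-18; adjusted p = 0.391 with an estimated correlation), with CYBB at 5.03 ± 0.09 and RAC2 at 2.10 ± 0.05. Specific granule genes rose in 9 of 12 and fell in 1 (median 1.78, adjusted p = 9.79e-07; adjusted p = 0.543 with an estimated correlation), with ANXA3 at 6.61 ± 0.16. Gelatinase granule and secretory vesicle genes rose in 10 of 12 and fell in 2 (median 1.39, adjusted p = 0.00232; adjusted p = 0.581 with an estimated correlation), with the integrin genes ITGAM up by 3.92 ± 0.12 and ITGB2 by 3.11 ± 0.06, while the gelatinase gene MMP9 fell by 1.66 ± 0.08. Azurophil granule genes rose in 13 of 21 and fell in 6 (median 1.00, adjusted p = 0.013; adjusted p = 0.581 with an estimated correlation), with HEXA at 1.18 ± 0.04. The median of the monocyte and macrophage markers was 1.93 (9 of 12 rose and 3 fell, adjusted p = 0.0113; adjusted p = 0.581 with an estimated correlation), with CX3CR1 at 6.13 ± 0.22, CD86 at 3.88 ± 0.13 and MS4A7 at -3.63 ± 0.18. Chemokine and cytokine genes rose in 6 of 12 and fell in 3 (median 0.67, adjusted p = 0.00106; adjusted p = 0.581 with an estimated correlation), with IL1B at 5.77 ± 0.16 and TNFSF13B at 3.06 ± 0.09. Sterol synthesis genes rose in 20 of 21 (median 0.82, adjusted p = 2.08e-04; adjusted p = 0.586 with an estimated correlation), with STARD4 at 2.15 ± 0.10 and DHCR7 at 1.78 ± 0.08. After a correction for GC content and length, with camera run on limma-voom values, the azurophil (adjusted p = 0.0575), monocyte (0.0546) and chemokine (0.201) lists were no longer called. Camera was not run on voom values without the correction, so these losses cannot be put down to GC content or length.

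MYC fell by 2.31 ± 0.07 (adjusted p = 2.0e-08), and of 27 MYC target and ribosome biogenesis genes 25 fell and 1 rose (median -0.58, adjusted p = 7.27e-05; adjusted p = 0.586 with an estimated correlation). GNL3 fell by 1.15 ± 0.05 and NPM1 by 1.07 ± 0.05. The other lists were not called by camera, with members in both directions. Of 29 myeloid transcription factors, 15 rose and 11 fell, with CEBPE at 3.45 ± 0.09, IRF1 at 2.85 ± 0.06 and CEBPB at 2.79 ± 0.08. Of 12 stem and progenitor markers, 1 rose and 7 fell, with SOX4 at -1.17 ± 0.06 and MYB at -1.08 ± 0.06. Of 12 eosinophil, basophil and mast cell markers, 3 rose and 6 fell, with HDC at -4.83 ± 0.13, GATA2 at -3.48 ± 0.22 and CCR3 at 3.22 ± 0.08. Cell cycle genes rose in 9 of 35 and fell in 20, with E2F1 at -0.94 ± 0.06 and MCM6 at -0.74 ± 0.06. Of 22 p53 and apoptosis genes 12 rose and 6 fell, with BCL2A1 at 7.37 ± 0.14 and BCL2 at -4.13 ± 0.09. Of 28 subunits of BAF, PBAF and ncBAF, 6 rose and 15 fell. BCL11A stood at -2.94 ± 0.06, SMARCD3 at -1.96 ± 0.14, SMARCC1 at -0.58 ± 0.04 and SMARCD1 at -0.33 ± 0.06. SMARCD2 itself stood at 0.53 ± 0.22 (adjusted p = 0.054), and at 0.51 (adjusted p = 2.9e-04) with the construct as a block. The value was 0.69 (adjusted p = 0.042) without hairpin 1 in DMSO and 0.71 (adjusted p = 0.0069) without hairpin 2 in ATRA, but 0.23 (adjusted p = 0.25) without hairpin 1 in ATRA. Of 22 unfolded protein and stress response genes 9 rose and 8 fell, with HSPA5 at 1.54 ± 0.05 and XBP1 at -1.27 ± 0.04, and the list median was 0.0025, or -0.13 with total counts. Lymphoid markers rose in 4 of 9 and fell in 2, with CD79A at 4.94 ± 0.12 and CD79B at -4.39 ± 0.16. Erythroid and megakaryocyte markers rose in 2 of 5 and fell in 1, with GATA1 at 1.10 ± 0.14.

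Adjusted over the list alone, the counts of higher and lower genes under ATRA were the same as over all genes in the lists above, except 26 lower MYC targets, 16 higher myeloid transcription factors and 7 lower p53 genes. The lymphoid list had a median of -0.04 but a mean of 0.35 and an upward test. The unfolded protein list had a mean of 0.02 and a downward test. No mitochondrially encoded transcript was in both tables, 0 of 13. Across the 4 comparisons tested, camera with its preset correlation called 30 of 76 shifts of lists, and 0 of the 30 held with an estimated correlation. That estimate rests on few residual degrees of freedom. With it, a list simulated as raised 1.3-fold also missed the threshold (camera adjusted p = 0.0693). So did the interferon list under ATRA, although 32 of 32 genes were called. A miss with it therefore does not show that a list was unshifted, and does not secure a preset call either. The fry test, which asks whether the genes of a list move on balance one way, called 16, and neither of its p-values compares a list with other genes. All p-values measure the spread between these libraries only, since the labels do not say whether they came from separate cultures.

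**Figure D2:**
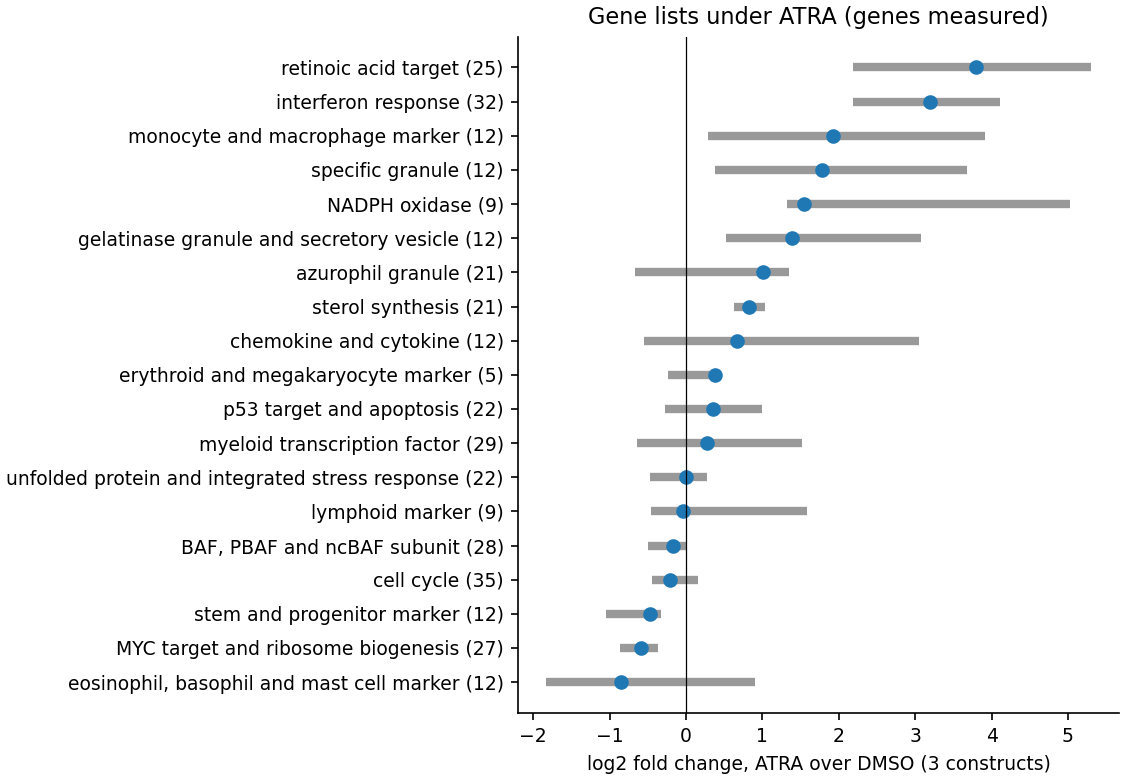
Median (points) and quartiles (bars) of the log2 fold change, ATRA over DMSO across the 3 constructs, for each gene list, with the number of genes measured in parentheses. The retinoic acid target (3.79) and interferon response (3.19) medians lie highest, and the MYC target median lies at -0.58. The unfolded protein median, 0.0025 here, is -0.13 when libraries are scaled to total counts.

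Some maturation genes were listed only in the ATRA table, so no fold change over DMSO was computed for them. Of 25 specific granule genes, 11 were such genes, including LTF, CAMP, MMP8, CEACAM8, OLFM4 and HP. The most abundant of the 537 genes listed only there, chosen after their values were seen, were the transglutaminase gene TGM2 at 3304 ± 370 CPM (SD, n = 3) and the retinoic acid hydroxylase gene CYP26A1 at 214 ± 10.7 CPM.

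The comparison of knockdown with control in DMSO asked what partial knockdown of SMARCD2 changes in undifferentiated cells. The growth factor gene HGF stood at 24.5 CPM in the control and at 59.2 and 99.4 CPM with the hairpins (log2 fold change 1.69 ± 0.30, SE, n = 2 against 1; adjusted p = 0.31). The Fc receptor genes FCGR2B (0.90 ± 0.13, adjusted p = 0.18) and FCGR2C (0.81 ± 0.09, adjusted p = 0.13), whose reads can be shared, were higher with both hairpins, as were RGS2 (0.85 ± 0.13), the vasodilator peptide gene ADM (0.81 ± 0.11) and the kinase gene SGK1 (0.81 ± 0.14). The metallothionein genes MT1G (0.95 ± 0.38) and MT1X (0.83 ± 0.29) were higher with both hairpins too, and their paralogs can share reads. Lower with both hairpins were TMEM160 at -1.07 ± 0.15 (73.5 CPM against 33.0 and 37.1, adjusted p = 0.18), NPW at -0.95 ± 0.18, CITED4 at -0.90 ± 0.18, LTB4R2 at -0.85 ± 0.17, CTU1 at -0.81 ± 0.18, CES1 at -0.74 ± 0.11, HAPLN4 at -0.73 ± 0.20 and CCDC85B at -0.72 ± 0.13. CEBPE, a granule gene regulator, had a log2 fold change of -0.02 ± 0.14. None of these genes passed the edgeR test, which called 0 of 12301 genes (868 at an unadjusted p under 0.05; smallest adjusted p 0.13), as did limma-voom, while DESeq2 called 32 higher and 6 lower. With the hairpin as a term, 85 genes were higher and 31 lower, with adjusted p of 4.7e-07 for HGF, 2.5e-04 for TMEM160, 3.1e-04 for FCGR2C, 0.0019 for FCGR2B, 0.0022 for ADM, 0.0073 for RGS2, 0.011 for SGK1, 2.2e-04 for CCDC85B, 0.0067 for CES1, 0.01 for NPW, 0.015 for CITED4 and 0.016 for LTB4R2. Without hairpin 1 in DMSO the group test called 20 genes higher and 1 lower. The authors' deposited table for DMSO calls 104 higher and 42 lower, in a test that may have counted runs as replicates.

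As groups, 8 lists shifted upward in DMSO by camera with its preset correlation. Interferon response genes were higher in 29 of 32 (median 0.33, adjusted p = 1.41e-17; adjusted p = 0.581 with an estimated correlation), with medians of 0.13 for hairpin 1 and 0.48 for hairpin 2. Adjusted over the list alone 1 of them passed. IFI44L stood at 0.94 ± 0.24 and IFIT3 at 0.65 ± 0.23. Sterol synthesis genes were higher in 18 of 21 (median 0.21, adjusted p = 7.36e-12; adjusted p = 0.581 with an estimated correlation) and 7 passed adjusted over the list alone, with the sterol carrier gene STARD4 at 0.52 ± 0.11 and INSIG1, a regulator of sterol sensing, at 0.49 ± 0.11. Gelatinase granule and secretory vesicle genes were higher in 11 of 12 (median 0.24, adjusted p = 1.97e-06; adjusted p = 0.581 with an estimated correlation; 4 adjusted over the list alone), with PLAUR at 0.54 ± 0.15 and ITGAM at 0.40 ± 0.16. Monocyte and macrophage markers had a median of 0.14 (adjusted p = 0.00102; adjusted p = 0.581 with an estimated correlation; 4 adjusted over the list alone), with MS4A7 at 0.79 ± 0.21 and FCGR1A at 0.46 ± 0.14. Their median was -0.0021 for hairpin 1 and 0.29 for hairpin 2, and without hairpin 2 in DMSO the adjusted p was 0.0649. Retinoic acid targets were higher in 19 of 25 (median 0.11, adjusted p = 0.00232; adjusted p = 0.581 with an estimated correlation; 1 adjusted over the list alone), with ICAM1 at 0.52 ± 0.23 and BHLHE40 at 0.40 ± 0.10. Myeloid transcription factors were higher in 21 of 29 (median 0.10, adjusted p = 0.00383; adjusted p = 0.581 with an estimated correlation; 1 adjusted over the list alone), with EGR1 at 1.16 ± 0.35 and KLF4 at 0.84 ± 0.23. The medians with hairpins 1 and 2 were 0.20 and 0.22 for the sterol list, 0.13 and 0.30 for the gelatinase list, 0.06 and 0.15 for the retinoic acid targets and 0.06 and 0.13 for the transcription factors. Without hairpin 1 in DMSO, IFIT3 stood at 0.95, ITGAM at 0.61, ICAM1 at 0.82 and EGR1 at 1.55. Without hairpin 2 in DMSO they stood at 0.34, 0.19, 0.20 and 0.70.

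The azurophil granule list had a median of 0.05 in DMSO (15 of 21 higher), with the proteinase gene PRTN3 at 0.81 ± 0.19 and AZU1 at 0.38 ± 0.10. The list's camera adjusted p was 0.0145, or 0.581 with an estimated correlation, and 4 genes passed adjusted over the list alone. Without hairpin 1 in DMSO its adjusted p was 0.0577. Chemokine and cytokine genes had a median of 0.30 (9 of 12 higher, adjusted p = 0.0208; adjusted p = 0.581 with an estimated correlation; 0 adjusted over the list alone), with CCL20 at 0.49 ± 0.18 and TNFSF13B at 0.33 ± 0.14. Without hairpin 2 in DMSO its adjusted p was 0.065. After the GC and length correction it was 0.0679 and with runs at equal depth 0.0546. TNFSF13B stood at 0.51 without hairpin 1 in DMSO and at 0.16 without hairpin 2. The medians with hairpins 1 and 2 were 0.04 and 0.08 for the azurophil and 0.17 and 0.22 for the chemokine list. With the hairpin term, the adjusted p of PRTN3 was 2.3e-04, of INSIG1 0.0022, of IFI44L 0.015, of MS4A7 0.015, of AZU1 0.02, of KLF4 0.033, of STARD4 0.037 and of EGR1 0.038. The erythroid and megakaryocyte list had a median of 0.14 and an upward test but a mean of -0.02.

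**Figure D3:**
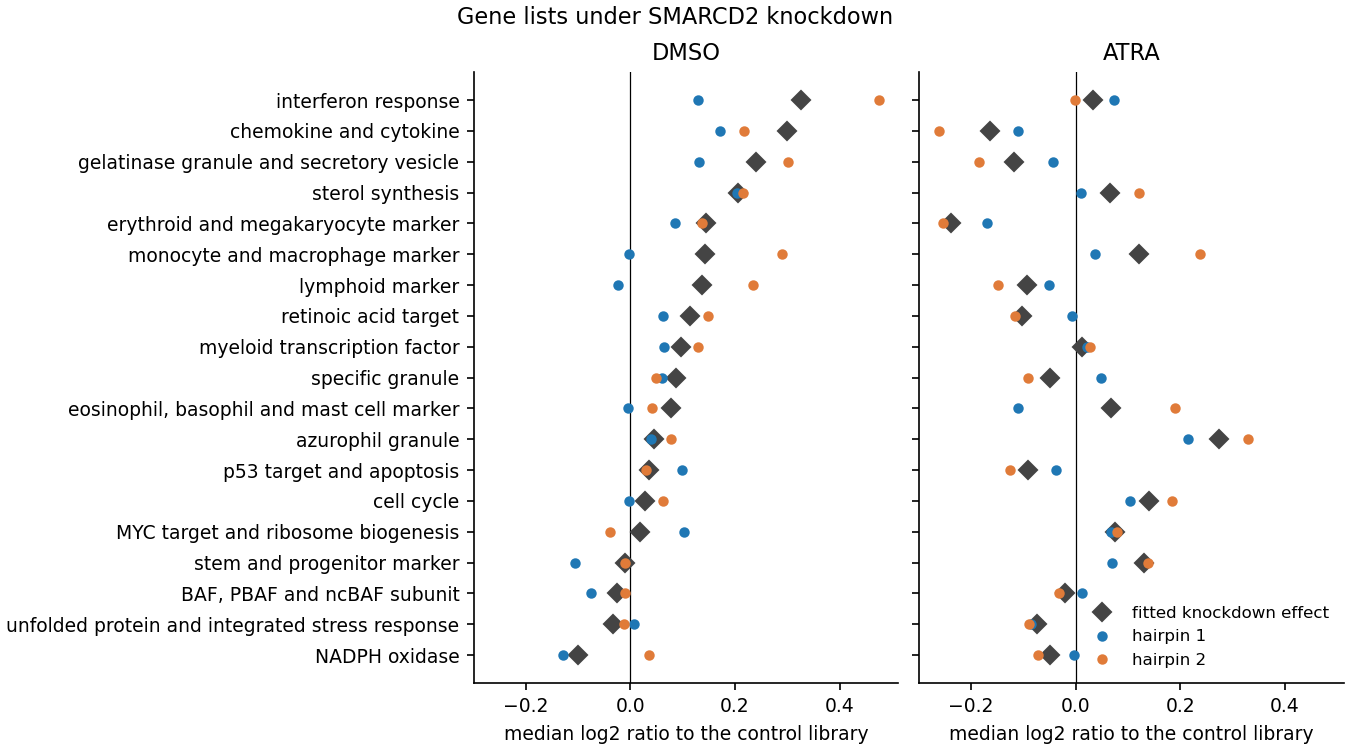
Median log2 ratio to the control library for each gene list in DMSO (left) and ATRA (right), as fitted over both hairpins (diamonds) and for each hairpin (circles). In DMSO the interferon response median is 0.13 with hairpin 1 and 0.48 with hairpin 2, and in ATRA the fitted azurophil granule median is 0.27.

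The comparison of knockdown with control in ATRA asked how partial knockdown of SMARCD2 alters differentiating cells. The glycolytic enzyme gene ENO2 fell from 35.5 CPM in the control to 11.7 and 10.3 CPM with the hairpins (log2 fold change -1.68 ± 0.10, SE, n = 2 against 1; adjusted p = 0.0038). It was the single gene to pass the edgeR test, and its adjusted p was 0.055 without hairpin 1 in ATRA and 0.058 without hairpin 2 in ATRA. A fit with the same knockdown effect in both treatments gave -0.60 (adjusted p = 0.73). PLD4 stood at 18.2 CPM in the control and at 30.9 and 62.2 with the hairpins (1.35 ± 0.40, adjusted p = 0.38), and also higher with both hairpins were PTGER2 at 1.00 ± 0.42, CLECL1 at 0.95 ± 0.25, VIT at 0.81 ± 0.26, the ficolin gene FCN1 at 0.77 ± 0.17, AK5 at 0.73 ± 0.22, PRTN3 at 0.71 ± 0.17 and ATL1 at 0.69 ± 0.20. Also lower with both hairpins were the innate receptor gene TREM1 at -1.06 ± 0.21, the chaperone gene CLGN at -1.06 ± 0.17, DOCK6 at -0.89 ± 0.09 (adjusted p = 0.083), NDRG1 at -0.85 ± 0.13, STX1A at -0.85 ± 0.10 and STRA6, a retinol transporter gene, at -0.82 ± 0.30. Without hairpin 1 in ATRA, PLD4 stood at 1.77 and PTGER2 at 1.29. Without hairpin 2 in ATRA they stood at 0.76 and 0.63. CEBPE stood at 0.01 ± 0.13, with 447 CPM in the control and 451 and 450 with the hairpins. edgeR called 0 genes higher and 1 lower of 12301 (1329 at an unadjusted p under 0.05), limma-voom also 1 lower, and DESeq2 18 higher and 36 lower. With the hairpin as a term, 149 genes were higher and 199 lower, with adjusted p of 9.4e-06 for NDRG1, 7.2e-05 for PLD4, 1.1e-04 for PRTN3, DOCK6 and STX1A, 0.0016 for CLGN, 0.0029 for FCN1, 0.011 for TREM1, 0.017 for CLECL1, 0.021 for ATL1, 0.022 for PTGER2, 0.024 for STRA6 and 0.03 for VIT. The authors' deposited table for ATRA calls 259 higher and 276 lower, in a test that may have counted runs as replicates.

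As groups in ATRA, cell cycle genes were higher in 32 of 35 with knockdown (median 0.14, camera adjusted p = 1.71e-08; adjusted p = 0.581 with an estimated correlation; 3 adjusted over the list alone), with the proliferation marker MKI67 at 0.44 ± 0.06 and RRM2 at 0.31 ± 0.07. Azurophil granule genes were higher in 16 of 21 (median 0.27, adjusted p = 2.47e-07; adjusted p = 0.543 with an estimated correlation; 7 adjusted over the list alone), with RNASE3 at 0.84 ± 0.25. Chemokine and cytokine genes were lower in 9 of 12 (median -0.16, adjusted p = 0.00102; adjusted p = 0.581 with an estimated correlation; 2 lower adjusted over the list alone), with CCL5 at -0.61 ± 0.11 and VEGFA at -0.59 ± 0.09. Sterol synthesis genes were higher in 16 of 21 (median 0.07, adjusted p = 0.0113; adjusted p = 0.704 with an estimated correlation; 0 adjusted over the list alone), with LSS at 0.47 ± 0.13. LSS stood at 0.61 without hairpin 1 in ATRA. Without hairpin 2 in ATRA it stood at 0.30, and the adjusted p of the list was 0.416. MYC targets were higher in 22 of 27 (median 0.08, adjusted p = 0.026; adjusted p = 0.728 with an estimated correlation; 0 adjusted over the list alone), with BOP1 at 0.25 ± 0.09 and LDHA at -0.32 ± 0.12. Their adjusted p was 0.0643 without hairpin 1 in ATRA and 0.0591 with the hairpin term. With that term the monocyte list shifted upward (adjusted p = 0.0204, against 0.094 without it), and the retinoic acid target (0.0419, against 0.0684) and unfolded protein lists (0.0394, against 0.125) shifted downward. Without that term the adjusted p with an estimated correlation was 0.689 for the monocyte, 0.633 for the retinoic acid target and 0.586 for the unfolded protein list, and the estimate was not run with it. The medians with hairpins 1 and 2 were 0.04 and 0.24 for the monocyte list, -0.0074 and -0.12 for the retinoic acid targets and -0.09 and -0.09 for the unfolded protein list. In a fit of the 3 libraries of the ATRA table, with all its genes, the monocyte list had a median of -0.02 (9 of 18 positive, adjusted p = 0.221). There camera called the retinoic acid targets (median -0.11, 29 genes, adjusted p = 0.00256) and the p53 list (median -0.10, 23 genes, adjusted p = 0.0371) downward, and the interferon list (median 0.02, 18 of 33 positive, adjusted p = 0.0205) upward. For each of these the adjusted p was 0.776 with an estimated correlation. The gene adjusted p with that term was 1.1e-04 for CCL5, 1.9e-04 for VEGFA, 0.0016 for MKI67, 0.0039 for LSS, 0.0066 for LDHA, 0.019 for RRM2 and 0.022 for RNASE3. The median and the test differed in sign for the myeloid transcription factors (median 0.01, mean -0.07, downward test) and for the eosinophil, basophil and mast cell markers (median 0.07, mean 0.02, downward test). For the BAF subunits the median was -0.02, the mean 0.02 and the test downward. The medians with hairpins 1 and 2 were 0.10 and 0.18 for the cell cycle, 0.21 and 0.33 for the azurophil, -0.11 and -0.26 for the chemokine, 0.0092 and 0.12 for the sterol and 0.07 and 0.08 for the MYC target list.

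The known human deficiency is an inherited loss of SMARCD2. Here the knockdown was partial, in a leukemia line. SMARCD2 stood in ATRA at 64.2 and 35.6 CPM with the hairpins against 122 in the control. Specific granule genes were set apart because of that deficiency, but their values are no direct test of it. The 12 listed in both tables had a knockdown median of 0.09 in DMSO (adjusted p = 0.532) and of -0.05 in ATRA (adjusted p = 0.487; 0.05 with hairpin 1 and -0.09 with hairpin 2), with 1 and 0 genes passing adjusted over the list alone. ORM1 stood at -0.997 ± 0.36 (0.019 with the hairpin term) and QSOX1 at -0.28 ± 0.10 in ATRA (0.037 with the hairpin term). Over the 23 genes of the ATRA table, in a fit of its 3 libraries, the median was 0.15 and camera called an upward shift (adjusted p = 0.0204; adjusted p = 0.776 with an estimated correlation). The smallest p there, chosen after it was seen, was that of CEACAM8. It stood at 5.50 CPM in the control and at 13.2 and 12.5 with the hairpins (1.23 ± 0.16, adjusted p = 0.11). CAMP stood at 0.83 ± 0.23, LTF at 0.55 ± 0.44 and MMP8 at 0.34 ± 0.11, and 0 specific granule genes passed in that fit. Over both tables, ORM1 stood at -1.61 without hairpin 1 in ATRA and at -0.58 without hairpin 2, and QSOX1 at -0.39 and -0.18.

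The test of the difference in ATRA response between knockdown and control asked which genes responded differently with SMARCD2 knockdown. The genes that passed were 6, all with a lower response in the knockdown cells, and ENO2, PFKFB4, ADM, BNIP3 and GBE1 are known targets of the hypoxia response or of glycolytic control. ENO2 moved from 26.0 to 35.5 CPM under ATRA in the control but from 40.6 to 11.7 with hairpin 1 and from 40.02 to 10.3 with hairpin 2 (log2 difference -2.32 ± 0.15, SE, n = 2 against 1; adjusted p = 0.0053). PFKFB4, a glycolysis regulator, moved from 32.4 to 117 CPM in the control, from 54.2 to 83.5 with hairpin 1 and from 55.4 to 77.7 with hairpin 2 (-1.30 ± 0.11, adjusted p = 0.018). ADM moved from 11 to 35.5 CPM in the control, from 19.0 to 22.4 with hairpin 1 and from 19.6 to 21.5 with hairpin 2 (-1.50 ± 0.14, adjusted p = 0.037). The osteopontin gene SPP1 moved from 2.40 to 220 CPM in the control, from 5.09 to 165 with hairpin 1 and from 5.2 to 153 with hairpin 2 (-1.56 ± 0.16, adjusted p = 0.044). The mitophagy gene BNIP3 (-1.10 ± 0.12) and the glycogen branching enzyme gene GBE1 (-0.92 ± 0.10) both had an adjusted p of 0.045. edgeR called 0 genes higher and 6 lower (979 at an unadjusted p under 0.05), limma-voom 2 and DESeq2 1 higher and 47 lower. By limma-voom the adjusted p was 0.334 for SPP1, 0.0573 for ADM and GBE1 and 0.0555 for BNIP3. SPP1 did not pass in run 1 alone (adjusted p = 0.0714), in run 2 alone (0.0892) or with runs at equal depth (0.0616), ADM not in run 2 alone (0.0768) or at equal depth (0.0616), and GBE1 not in run 1 alone (0.0713). With the hairpin as a term 16 were higher and 113 lower. Leaving out any 1 knockdown library left ENO2 past the threshold (adjusted p 0.027 without hairpin 1 in DMSO, 0.029 without hairpin 2 in DMSO, 0.044 without hairpin 1 in ATRA and 0.039 without hairpin 2 in ATRA), with PFKFB4 beside it only without hairpin 1 in DMSO (adjusted p = 0.047). Each of these fits keeps 1 knockdown library in 1 treatment, assumed to vary like the others, and takes all its spread from the 2 hairpins in the other treatment.

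**Figure D4:**
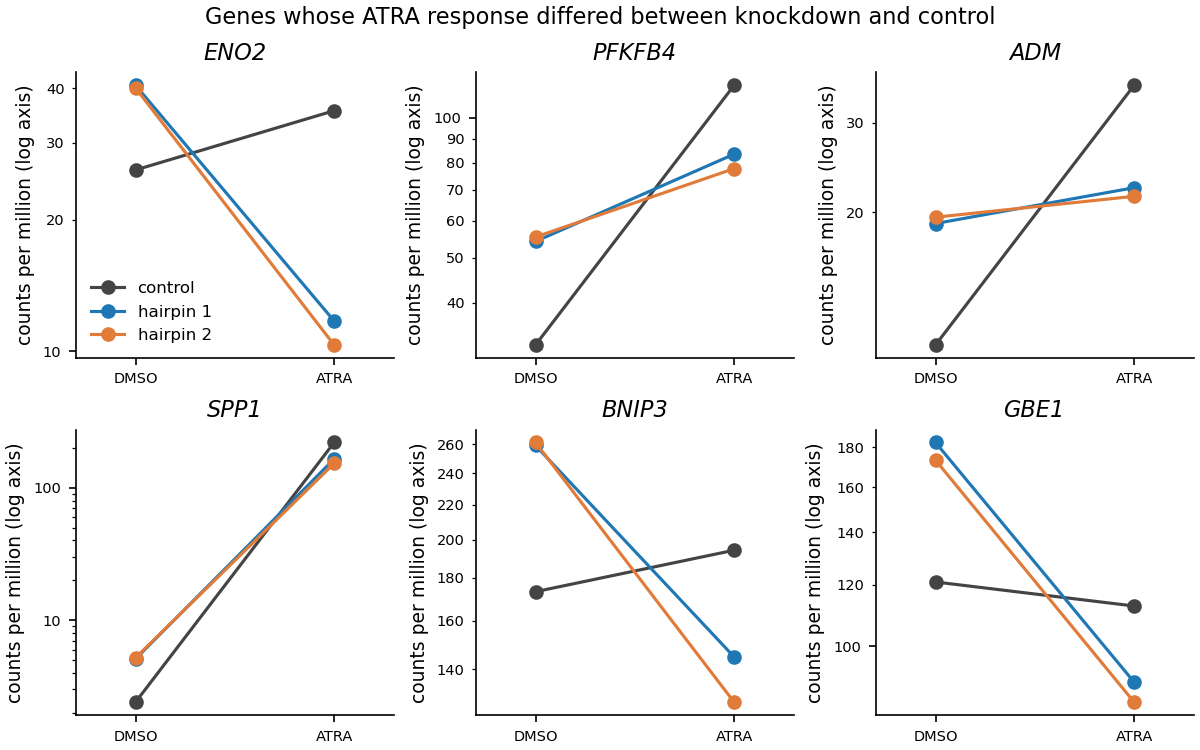
CPM (log axis) of the 6 genes that passed the test of a different ATRA response, 1 line per construct from DMSO to ATRA. ENO2 rose from 26.0 to 35.5 in the control and fell to 11.7 and 10.3 with the hairpins.

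Beyond these 6 genes, NDRG1 (-1.36 ± 0.19, adjusted p = 0.079) and the heat shock gene HSPA6 (-1.86 ± 0.35) had negative differences with both hairpins, and positive with both were PLD4 (1.22 ± 0.66), TGFA (1.15 ± 0.24), DAPK2 (1.05 ± 0.27), ANKRD35 (1.04 ± 0.30) and AMH (0.99 ± 0.28). With the hairpin as a term the adjusted p was 5.3e-06 for NDRG1, 0.0073 for HSPA6, 0.019 for TGFA and 0.021 for PLD4. Interferon response genes had a lower ATRA response with knockdown in 31 of 32 (median -0.30 fitted over both hairpins, -0.04 with hairpin 1 and -0.48 with hairpin 2; camera adjusted p = 9.79e-07; adjusted p = 0.636 with an estimated correlation; 0 adjusted over the list alone), with IFI44L at -0.95 ± 0.30 and OASL at -0.80 ± 0.32. Gelatinase granule and secretory vesicle genes had a median of -0.39 (-0.13 with hairpin 1 and -0.49 with hairpin 2; adjusted p = 5.50e-05; adjusted p = 0.581 with an estimated correlation; 3 lower adjusted over the list alone), with the Fc receptor gene FCAR at -1.87 ± 0.50 and PLAUR at -0.98 ± 0.21. Chemokine and cytokine genes had a median of -0.37 (-0.18 and -0.48; adjusted p = 2.68e-04; adjusted p = 0.581 with an estimated correlation; 2 lower adjusted over the list alone), with CCL5 at -0.94 ± 0.15 and CCL20 at -0.69 ± 0.24. Retinoic acid targets had a median of -0.17 (-0.08 and -0.24; adjusted p = 5.42e-04; adjusted p = 0.581 with an estimated correlation; 2 lower adjusted over the list alone), with STRA6 at -1.53 ± 0.51 and the retinal reductase gene DHRS3 at -1.21 ± 0.24. Without hairpin 1 in DMSO, OASL stood at -1.11 and STRA6 at -2.001. Without hairpin 2 in DMSO they stood at -0.497 and -0.97. PLD4 stood at 1.64 without hairpin 1 in ATRA and at 0.61 without hairpin 2 in ATRA.

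Cell cycle genes had a higher response with knockdown, with a median of 0.14 (0.12 with hairpin 1 and 0.13 with hairpin 2; 23 of 35 positive, adjusted p = 7.86e-04; adjusted p = 0.581 with an estimated correlation; 0 adjusted over the list alone), including TK1 at 0.48 ± 0.14 and MCM5 at 0.37 ± 0.12. Sterol synthesis genes had a median of -0.11 (-0.18 and -0.05; 17 of 21 negative, adjusted p = 0.014; adjusted p = 0.704 with an estimated correlation; 0 adjusted over the list alone), with STARD4 at -0.42 ± 0.15, and the adjusted p was 0.48 without hairpin 1 in ATRA. Myeloid transcription factors had a median of -0.09 (-0.06 and -0.08; 18 of 29 negative, adjusted p = 0.0297; adjusted p = 0.586 with an estimated correlation; 3 lower adjusted over the list alone), with EGR1 at -1.75 ± 0.44, and the adjusted p was 0.0649 without hairpin 2 in DMSO, 0.0787 after the GC and length correction and 0.0608 with runs at equal depth. With the hairpin as a term the p53 and apoptosis list (median -0.14) shifted downward too (adjusted p = 0.0462, against 0.0684 without it; without it the adjusted p = 0.581 with an estimated correlation). With the term the adjusted p of CCL5 was 7.2e-05, of PLAUR 0.011, of EGR1 0.012, of DHRS3 0.028, of FCAR 0.03 and of STRA6 0.0496. The NADPH oxidase list had a median of -0.04, a mean of 0.0077 and a downward test, and the monocyte list a median of 0.09, a mean of -0.04 and a downward test.

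The hairpins were compared with each other over both treatments, to set their difference beside the knockdown effect. Besides SMARCD2, 3 of 12 eosinophil, basophil and mast cell markers passed, named after their values were seen (list median 0.28, with no test of the list), against 250 of 12300 genes in all. PRG2 was higher with hairpin 2 by 0.58 ± 0.04 (SE, n = 2 against 2; adjusted p = 3.4e-08), EPX by 0.62 ± 0.07 (adjusted p = 1.9e-05) and PRG3 by 1.14 ± 0.19 (adjusted p = 0.0011). The receptor kinase gene FLT3 was higher by 0.72 ± 0.10, the BAF subunit gene BCL7A by 0.79 ± 0.09, the monocytic regulator IRF8 by 0.48 ± 0.09 and PRTN3 by 0.35 ± 0.06. By DESeq2 the adjusted p was 0.226 for PRG3 and 0.12 for IRF8. edgeR called 160 genes higher and 90 lower with hairpin 2 of 12300 tested, limma-voom 266 and 175, and DESeq2 29 and 20. The hairpins' log2 ratios to the shared control correlated across genes with r = 0.58 in DMSO, against 0.54 simulated for unchanged hairpins, and with r = 0.70 in ATRA, against 0.54. The covariance was 0.0241 in DMSO against 0.0172 simulated, and 0.0327 in ATRA against 0.0177. The same sign in both hairpins held for 69.9% of genes in DMSO (67.7% simulated) and for 76.7% in ATRA (67.6% simulated). Part of the excess may come from the shared control, which is 1 library per treatment and was not split, and genes are not independent replicates. The fitted knockdown effects in DMSO and in ATRA correlated across genes with r = 0.098.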

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

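The tests of sequencing runs, of GC content and of a wider hypoxia response for the interaction genes were chosen after the result was seen; the tests on the interferon genes and on other splits of the libraries were set down before their values were seen.

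A test of the difference itself singled out 6 genes whose ATRA response was lower with knockdown than in the control: ENO2 (log2 difference -2.32), SPP1 (-1.56), ADM (-1.50), PFKFB4 (-1.30), BNIP3 (-1.10) and GBE1 (-0.92). Each had a higher level than the control with both hairpins in DMSO and a lower level with both in ATRA. Both hairpins share 1 control library per treatment, so their agreement is not separate support. A mix of sequencing runs that differs between libraries is argued against, since the median of the 6 was -1.45 in run 1 alone and -1.30 in run 2 alone (SPP1 missed the threshold in both, GBE1 in run 1 and ADM in run 2), as is a GC or length trend, after whose removal it was -1.38. A wider hypoxia response is a candidate explanation: of the other 31 genes of a hypoxia list, 31 had a lower ATRA response with knockdown, with a median of -0.46 against -0.07 to 0.05 for the central 95% of random lists, and 22 passed adjusted over the list alone (0 over all genes). The list was written with the called genes in view, and without ALDOC and PLIN2, whose values had been seen by then, the median was -0.43. NDRG1, BHLHE40, VEGFA and LDHA, named from the same gene tests, stayed in, so this is not a median over unseen genes. Random lists also do not allow for correlation between the genes of a list, which was not estimated for this one. With 1 control library per treatment, a difference in cell density or oxygen between the control and knockdown cultures stays open beside an effect of SMARCD2 knockdown, and neither was tested.

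The test of the difference also called 7 lists, and 0 of them held with an estimated correlation, which also missed the list simulated as raised. The largest was the gelatinase granule and secretory vesicle list with a median difference of -0.39 (-0.13 with hairpin 1, -0.49 with hairpin 2). The chemokine and cytokine median was -0.37 (-0.18, -0.48). The retinoic acid target median was -0.17 (-0.08, -0.24). The sterol synthesis median was -0.11 (-0.18, -0.05). The myeloid transcription factor median was -0.088. The cell cycle median was 0.14. The interferon response median was -0.30, at -0.04 with hairpin 1 and -0.48 with hairpin 2.

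In DMSO the interferon response genes had a median of 0.33 over the control, while in ATRA it was 0.03 (0.02 over the 33 genes of the ATRA table, where camera called an upward shift, adjusted p = 0.0205; adjusted p = 0.776 with an estimated correlation), and ATRA raised all 32 in the constructs together. An unequal mix of runs is argued against by medians of 0.32 in run 1 alone and 0.33 in run 2 alone, and a GC or length trend by a median of 0.33 after its removal. A response to 1 hairpin cannot be told apart from a response to knockdown here, because the lower median, 0.13 with hairpin 1, lies between the bounds set for either (0.48 with hairpin 2), although 26 and 31 of the 32 genes stood above the control. An effect of SMARCD2 knockdown and a lower state of the single control library could both give such a shift.

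The ATRA response over the constructs rested on 3 libraries against 3, and 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 9100 genes, 1 of the 10 splits gave as many, and the highest of the others gave 0.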

How the results depend on the processing

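The alternatives with runs or with a GC and length correction were chosen after seeing the data. The ATRA counts (control, knockdown and over the constructs) stayed within 1.5 times under every alternative run, and 160 named gene values were refitted to 2853 values, of which 2634 kept their direction and side of the threshold, 34 no longer passed it, 176 newly passed it and 9 reversed. For knockdown in DMSO (0 genes), DESeq2 gave 38, the replicate block of hairpins 116, run 2 alone 3, each run as a library 681, and leaving out a library 0 to 21. For knockdown in ATRA (1 gene), these gave 54, 348, 7, 1559 and 0 to 1, and the additive fit 0. For the difference in ATRA response (6 genes), DESeq2 gave 48, limma-voom 2, the block 129, the block with GC correction 127, each run as a library 923 and leaving out a library 1 to 2. Between the hairpins (250 genes), DESeq2 size factors gave 382, DESeq2 49, limma-voom 441, equal depth 118 and each run as a library 1433; leaving out a library leaves no residual degrees of freedom. Each run as a library counts technical runs as replicates, which lowers its error. The block removes the hairpin difference, and with it the spread between constructs that knockdown against control needs. The cause of the other shifts was not tested. The hairpin correlation in ATRA was 0.76 at a mean of at least 10 CPM, against 0.52 simulated for unchanged hairpins. Of the 30 list calls, 0 held with an estimated correlation, which also missed the list simulated as raised. The fry test called 16, 10 of them shared. Tests within 1 table, which leave out the ATRA and interaction comparisons, called 17, 13 of them shared. With GC correction, run for lists on limma-voom values, 5 ended, of which the ATRA lists were azurophil (0.0575), monocyte (0.0546) and chemokine (0.201). The others were DMSO chemokine (0.0679) and interaction transcription factors (0.0787), and these 2 also ended at equal depth (0.0546 and 0.0608). Reversed values, all of genes that were not called, were CEBPE in DMSO (-0.22 to 0.16 leaving out a library), ADM (-0.042), PLAUR (-0.0046) and BHLHE40 (-0.14) in DMSO with the additive fit, and CEBPE in ATRA with the additive fit (-0.0038), run 1 (-0.048), run 2 (-0.045), equal depth (-0.039) and each run as a library (-0.046). Among the genes and lists named, the pairing changed no call other than those given beside the results. It moved the ATRA counts to 7785 genes in the control, 9073 in the knockdown cells and 9132 over the constructs, 9021 of the last shared with the 9100. Removing the filter changed no gene tested except 1 for the hairpins, and alternatives for normalized values were not run because the files hold counts. In simulation 9% of genes with a 1.5-fold difference in response were called, so differences of that size were rarely detected.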

Other observations

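Both tests here, of hypoxia and of metallothionein genes, were chosen after the gene tests had been seen, and their random lists do not allow for correlation between genes. The 31 hypoxia response genes outside the 6 interaction genes had a median knockdown effect of 0.21 in DMSO (28 of 31 positive, against -0.03 to 0.05 for the central 95% of random lists matched on expression) and of -0.29 in ATRA (31 of 31 negative, against -0.05 to 0.05). Adjusted over the list alone, 16 were higher in DMSO and 19 lower in ATRA, and 0 in either were called over all genes by edgeR. The medians held for each hairpin, at 0.24 and 0.19 in DMSO and at -0.20 and -0.37 in ATRA. VEGFA, NDRG1, LDHA and BHLHE40 belong to this list, and so the knockdown values of those genes and of the 6 interaction genes are not separate observations.

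The 7 measured metallothionein genes, fitted over both hairpins, had a median knockdown effect of 0.83 in DMSO (7 of 7 positive, random lists -0.20 to 0.17) and of 0.87 in ATRA (7 of 7 positive, random lists -0.23 to 0.18). MT1G and MT1X, already named from the same gene tests, were kept in the list. The random lists do not allow for that choice or for reads shared between paralogs, so they cannot show how unusual these medians are. The medians with hairpins 1 and 2 were 0.61 and 0.88 in DMSO and 0.35 and 1.03 in ATRA, where MT1X with hairpin 1 stood below the control (4.12 against 4.29 CPM). Adjusted over the list alone, 4 passed in DMSO and 3 in ATRA, and 0 over all genes by edgeR. MT2A stood at 33.2 CPM in the control in DMSO against 50.9 and 58.3 with the hairpins, and at 39.6 against 50.5 and 69.1 in ATRA. MT1A had nearly the same values as MT2A in every library (34.9, 53.5 and 63.4 CPM in DMSO), and reads of such paralogs can be shared, so the genes do not count as separate observations.

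In the authors' deposited tables, 11300 genes have an adjusted p in both treatments. The authors' deposited tables call 9 genes higher with knockdown in both (2.08 for independent lists), 4 lower in both (0.914), 25 higher in DMSO and lower in ATRA (2.27), and 0 lower in DMSO and higher in ATRA (0.835). The control libraries differ between the treatments, so these calls share no control. Within a treatment they rest on 1 control library, and the authors' test may have counted its runs as replicates. The 25 genes higher in DMSO and lower in ATRA include ENO2, PFKFB4, ADM, SPP1, BNIP3, GBE1 and NDRG1. They are thus not separate from the interaction and hypoxia response values above. The values for independent lists also do not allow for correlation between genes.

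Among the 451 genes listed only in the DMSO table, the most abundant was CHAT at 55.4 ± 3.33 CPM (SD, n = 3), and ELANE and ERG were 2 of the 8 list members among them. Across 12264 genes, which are not independent replicates, the knockdown effect correlated with GC content at rho = -0.17 in DMSO and -0.04 in ATRA.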
